A study of Mus musculus with 7 samples.

How the data were processed

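RNA was measured by sequencing in bone marrow cells of individual C57BL/6 mice, in 7 libraries of 6 groups. The HSC/P groups were HMGA2-OE (1 library) and RUNX1mut/HMGA2-OE (2 libraries), and the Ly6G+ groups were Control, RUNX1mut, HMGA2-OE and RUNX1mut/HMGA2-OE (1 library each). The submitters' processing notes name bcl2fastq, CASAVA 1.8 and kallisto with the mouse genome build mm10. The annotation release, the version of kallisto and its index are not given in the sources used here. The deposited table holds TPM made by the authors, as read from the values, since no header names a unit and the file is called a table of counts: the values are not whole numbers and each column sums to nearly the same total, between 896820 and 993009. It lists 28987 genes by Ensembl identifier, of which 22784 were above 0 in a library. Symbols and coordinates came from GENCODE M21 for 27458 identifiers, and the 1529 others took at most 1.67% of TPM in a library. All columns of the table were used. TPM carries no read counts, so the depth per library and the counting error of each value are unknown.

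A test for counts had been planned. Because the table holds TPM, that test was replaced by limma on log2 of scaled TPM with 1 TPM added, and the planned filters on counts by filters on TPM. Genes with at least 1 TPM in at least 2 libraries of a fit were kept. Libraries were scaled by an unweighted trimmed mean of log ratios (trims 0.3 and 0.05) over the genes of each fit, and variances were moderated with a trend on mean expression. Fold changes are on this log2 scale, which understates those of genes with low TPM. Each test was two-sided with Benjamini-Hochberg adjustment at 0.05. The ± values are standard errors of the fit. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

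There were 6 tested comparisons: RUNX1mut/HMGA2-OE against HMGA2-OE in the 3 HSC/P libraries, the RUNX1 term and the HMGA2-OE term of an additive fit to the 4 Ly6G+ libraries, and, in the 5 libraries with HMGA2-OE, the effect of the RUNX1 mutation over both cell types, HSC/P against Ly6G+ and the interaction of mutation and cell type. Single Ly6G+ libraries were also compared by log2 ratios with 1 TPM added, without a test. A list's median ratio was placed among those of 10000 random lists of the same size matched on mean expression, as a description of these libraries. Counts of genes at least 2-fold the same way in separate pairs were set beside the product of the single counts over the genes.

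The comparisons, 28 gene lists, the rule for named genes and a part of the other settings tried were fixed before the data were examined. The lists were the HMGA2 and let-7 axis, stem and progenitor, reported RUNX1 targets, primary granule, secondary and tertiary granule, mature neutrophil, monocyte and macrophage, erythroid, megakaryocyte and platelet, eosinophil with basophil and mast cell, B lymphoid, T and NK cell, stromal and endothelial, MHC class II, interferon response, NF-kB targets, immediate early and heat shock, JAK-STAT targets, cell cycle, p53 targets, unfolded protein response, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal protein, NADPH oxidase, sex-linked and mitochondrially encoded genes. Of 423 memberships 417 were in the table, for 406 distinct genes, so some genes are in several lists. Lists were tested in limma by camera with a preset correlation between genes of 0.01, by camera with an estimated correlation and by fry, where at least 5 members were tested. Stromal and endothelial and sex-linked genes fell short of that in every fit, and T and NK cell genes in the fits with HSC/P libraries, so they have no result there.

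The text names Hmga2 and Runx1 for every library. For each test it names the 10 genes with the largest rise and the 10 with the largest fall among those that passed and reached 10 TPM. Where fewer than 5 passed in a direction, it names the 5 with the smallest p, as values that did not pass. For the pairs it names genes at least 2-fold the same way in both, ranked by the smaller change, and from each list up to 4 members. Clone names and pseudogenes were counted and not named, and some genes that the rule names are not reported here and were not replaced, though they stay in every fit and list. Other genes are said to have been chosen after their values were seen.

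The procedure was tested on simulated data with 200 changed genes in each of 5 rounds. The changed genes were drawn from those averaging about 10 TPM or more, so recovery among genes of lower TPM was not measured. A first version drew variances from the fitted values per gene and gave too many false calls, so the simulation was redone with variances drawn from the fitted prior distribution. In HSC/P it then recovered 1.2%, 59.2%, 91.6% and 95.2% of genes changed 2, 4, 8 and 16-fold, and for the RUNX1 term in Ly6G+ cells 0%, 21.6%, 68.1% and 83.0%. The HMGA2-OE term recovered 0%, 16.8%, 63.7% and 81.4%, and the interaction recovered 0 genes at any of these sizes. False calls averaged at most 8.6 per round. The simulated variances followed the distribution that the test assumes, so this figure does not show the false calls in data that depart from it. A list shifted 2-fold was called in 5 of 5 rounds with the preset correlation and in 0 of 5 with an estimated one, and 0 of 120 unshifted lists were called in each comparison. The simulated genes varied independently, so the simulation cannot show how often lists of correlated genes are falsely called. In the HSC/P data the estimated correlation ranged from -0.06 for NF-kB targets to 1 for megakaryocyte genes. That fit has 1 residual degree of freedom, so the estimate rests only on the difference within the replicate pair. Since the shifted list was never called with an estimated correlation, a list that did not pass with it is not thereby argued against.

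The alternatives were other scalings (relative log expression, upper quartile, none), no filter or at least 5 TPM, 0.5 or 5 TPM added, no variance trend, robust variances, fits to all 7 libraries, each library left out, and leaving out genes with a transcript under 300 nt or of 350 to 420 nt. Reads were not used here. Endogenous, mutant and introduced transcripts were not separated, since the table is per gene.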

Results

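RNA sequencing was used to profile bone marrow cells of C57BL/6 mice in 7 libraries. In 3 libraries the cells were hematopoietic stem and progenitor cells (HSC/P), enriched for the receptor CD117 and then sorted for the mutant clone. In the other 4 libraries they were sorted Ly6G+ myeloid cells, which are mostly neutrophils. The genotypes were overexpression of HMGA2 (HMGA2-OE), mutation of RUNX1 (RUNX1mut), both together (RUNX1mut/HMGA2-OE) and control. The HSC/P libraries were 1 of HMGA2-OE and 2 of RUNX1mut/HMGA2-OE. The Ly6G+ libraries were 1 of each of the 4 genotypes, so no Ly6G+ genotype had a replicate. Values were length-normalized transcript shares (TPM), and read depth per library is unknown. The listed genes summed to between 896820 and 935711 TPM in HSC/P and between 984650 and 993009 TPM in Ly6G+ cells. Between 12012 and 12449 genes reached 1 TPM in HSC/P, and between 8559 and 10763 did in Ly6G+ cells. Over 12226 genes the RUNX1mut/HMGA2-OE HSC/P pair had a Pearson r of 0.967 across genes, which are not independent replicates, and 95.3% of genes lay within 2-fold.

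S100a8 and S100a9, which encode the subunits of the neutrophil protein calprotectin, took a large part of the Ly6G+ transcripts. Their shares were singled out after the values were seen. S100a8 made up 43.9% of TPM in Control, 39.9% in RUNX1mut and 54.6% in HMGA2-OE, against 3.06% in RUNX1mut/HMGA2-OE. S100a9 made up 8.36%, 8.20%, 7.07% and 14.2% of TPM in the same order. The S100a8 to S100a9 ratio was thus 0.216 in the RUNX1mut/HMGA2-OE Ly6G+ library and between 4.86 and 7.72 in the other 3. In HSC/P the ratio lay between 1.63 and 2.25, and S100a8 took 3.39% of TPM in HMGA2-OE and 1.12% and 0.969% in the RUNX1mut/HMGA2-OE pair.

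**Figure D1:**
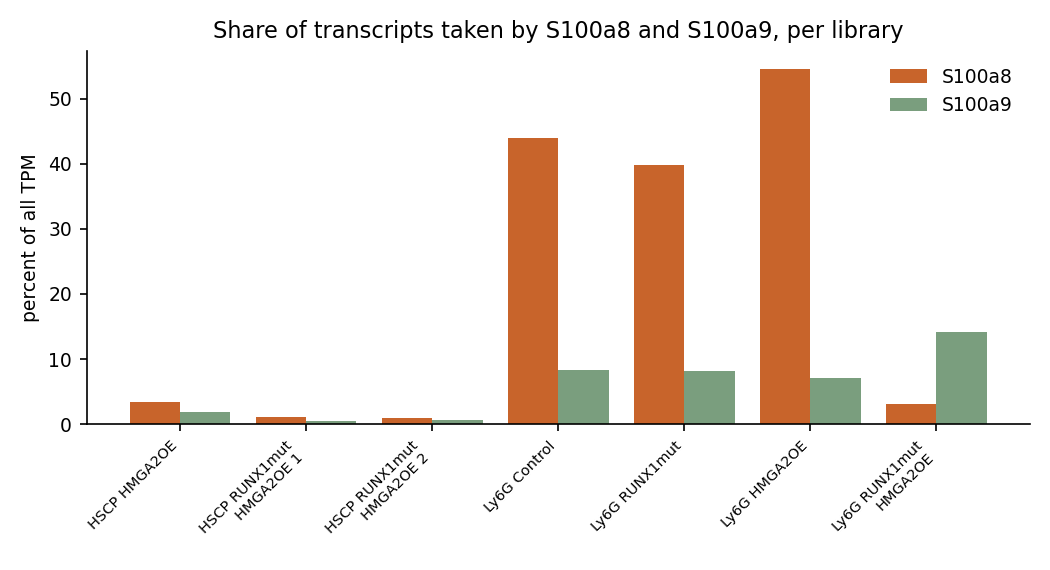
Share of all TPM (percent, y axis) taken by S100a8 and S100a9 in each of the 7 libraries (x axis, 1 bar per gene and library, no error bars). S100a8 exceeds S100a9 in 6 libraries and is below it in the RUNX1mut/HMGA2-OE Ly6G+ library, at 3.06% against 14.2%.

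Hmga2 RNA was higher in the Ly6G+ libraries labelled HMGA2-OE, and Runx1 RNA was higher in the libraries labelled RUNX1mut. All 3 HSC/P libraries carry HMGA2-OE, so Hmga2 has no reference there. Hmga2 (ENSMUSG00000056758, mm10 chromosome 10, 120361275 to 120476469, minus strand), which encodes a chromatin architectural protein, was measured at 147 TPM in HMGA2-OE HSC/P and at 176 and 138 TPM in the RUNX1mut/HMGA2-OE HSC/P pair. In Ly6G+ cells it was at 1.45 TPM in Control, 1.36 in RUNX1mut, 3.72 in HMGA2-OE and 12.1 in RUNX1mut/HMGA2-OE. After scaling between these libraries the values were 1.61, 1.33, 5.40 and 7.64. Runx1 (ENSMUSG00000022952, mm10 chromosome 16, 92601466 to 92826149, minus strand), a transcription factor needed for definitive blood formation, was measured at 18.9 TPM in HMGA2-OE HSC/P and at 219 and 225 TPM in the RUNX1mut/HMGA2-OE pair. In Ly6G+ cells Runx1 was at 3.85 TPM in Control and 3.36 in HMGA2-OE, against 11.6 in RUNX1mut and 21.2 in RUNX1mut/HMGA2-OE, or 4.28 and 4.88 against 11.4 and 13.5 after scaling. The files do not separate endogenous from introduced or mutant transcripts. Its relative Runx3 showed the same order, with 19.8 TPM in HMGA2-OE HSC/P against 338 and 245 in the RUNX1mut/HMGA2-OE pair, and 1.65 and 1.81 TPM in Ly6G+ cells without the mutation against 14.3 and 71.2 with it (1.83 and 2.62 against 14.1 and 45.1 after scaling). Runx3 has an annotated transcript of 350 to 420 nt, a class weighed in the closing section, and reads shared between these relatives were not examined. Runx2, singled out after its values were seen, was at 8.49 TPM in HMGA2-OE HSC/P and at 24.5 and 23.2 in the pair, and in Ly6G+ cells at 4.44 in Control and 5.57 in RUNX1mut, 4.12 in HMGA2-OE and 25.2 in RUNX1mut/HMGA2-OE.

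**Figure D2:**
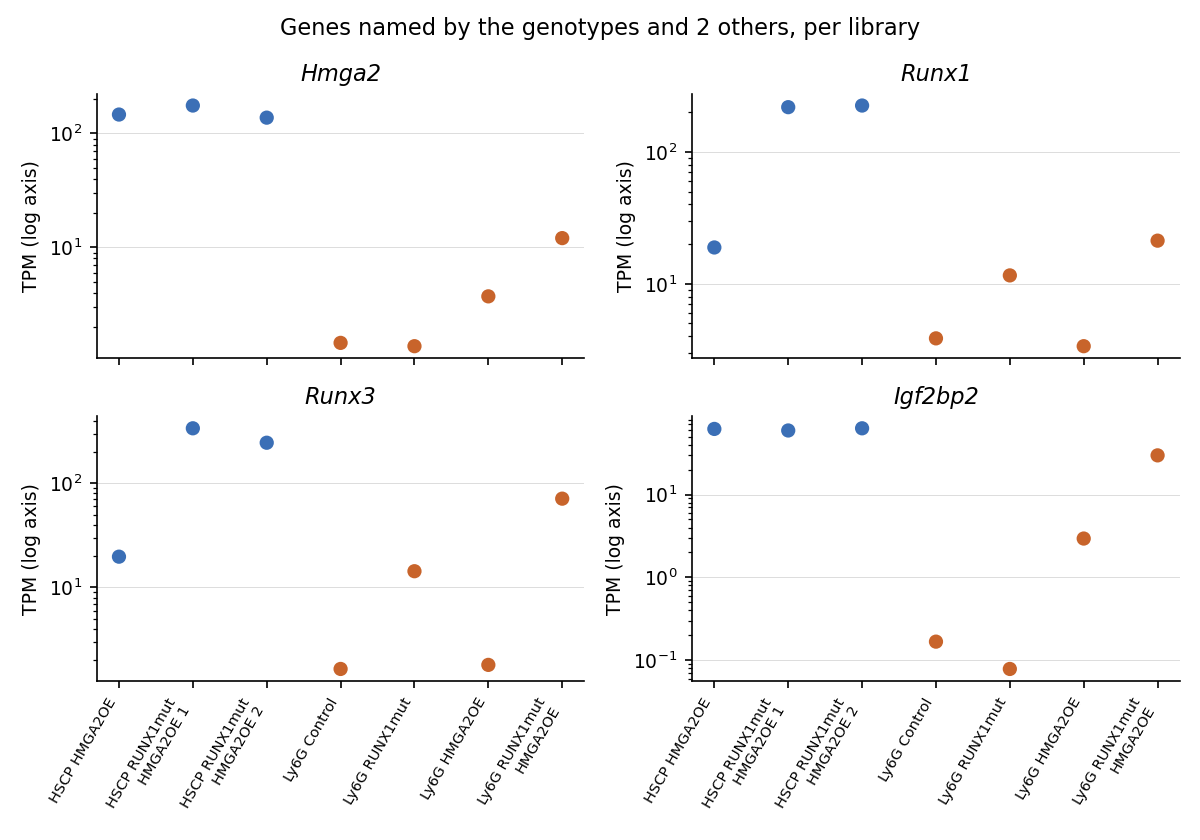
TPM (log axis) of Hmga2, Runx1, Runx3 and Igf2bp2 in each of the 7 libraries, 1 point per library, HSC/P in blue and Ly6G+ in orange. Runx1 and Runx3 are higher in every library with the RUNX1 mutation than in those of the same cell type without it, and Hmga2 and Igf2bp2 are higher in Ly6G+ cells with HMGA2-OE than without.

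The first comparison asked what the RUNX1 mutation added to HMGA2-OE in HSC/P, with 2 libraries against 1. Granule and other neutrophil genes, erythroid genes and cell cycle genes were lower in RUNX1mut/HMGA2-OE, while megakaryocyte, MHC class II and stem or progenitor genes were higher. The secondary and tertiary granule genes, which encode proteins of maturing neutrophils, were lower for 20 of 20 members, with a median log2 fold change of -1.93. Olfm4 differed by -4.88 ± 0.23 (SE) on the log2 scale, the gelatinase gene Mmp9 by -2.67 ± 0.18, and Lcn2, whose product binds iron-carrying siderophores, by -2.37 ± 0.17. The megakaryocyte and platelet genes were higher for 14 of 14 members, with a median of 2.55. The RUNX1mut/HMGA2-OE libraries stood apart on this list, with a median of 1.77 for replicate 1 and 3.13 for replicate 2 over HMGA2-OE, and Pf4 was at 339 and 983 TPM against 355 in HMGA2-OE. Among its members were the integrin genes Itga2b (4.09 ± 0.46) and Itgb3 (2.90 ± 0.33) and Treml1, a receptor of platelet granules (4.30 ± 0.69).

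Of the granule genes, 20 of 20 passed when adjusted over the list alone, and the list fell as a set (camera adjusted p = 1.3e-17), with adjusted p = 0.799 with an estimated correlation. The mature neutrophil list had a median of -0.48 (14 of 22 lower; 9 lower and 2 higher passed adjusted over the list alone; camera adjusted p = 0.0279). In it S100a9 differed by -1.99 ± 0.14 and the formyl peptide receptor gene Fpr2 by -2.86 ± 0.22, while the lectin gene Clec4d differed by 1.92 ± 0.21. The primary granule list had a median of -0.64 (11 of 12 lower, 3 adjusted over the list alone; camera adjusted p = 0.00247), with Nkg7 at -2.56 ± 0.15 and the ficolin gene Fcnb at -2.26 ± 0.37. The NADPH oxidase list, whose products make the neutrophil oxidative burst, had a median of -0.62 (7 of 9 lower, 4 adjusted over the list alone; camera adjusted p = 0.00512), with its catalytic subunit Cybb at -2.01 ± 0.22. The monocyte and macrophage list had a median of -0.33 (12 of 16 lower, 1 adjusted over the list alone, Ly6c2; camera adjusted p = 0.0421), and without the second RUNX1mut/HMGA2-OE library its median was 7.05e-05. With an estimated correlation the mature neutrophil, primary granule and NADPH oxidase lists had adjusted p = 0.799 and the monocyte list adjusted p = 0.830. Beside these, Ly6g, the antigen by which the mature cells were sorted and singled out after its values were seen, was at 136 TPM in HMGA2-OE HSC/P and at 7.28 and 16.8 TPM in the pair.

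The 5 other called lists each had adjusted p = 0.799 with an estimated correlation. The erythroid list fell, with 17 of 17 members lower, a median of -0.99 and 8 members adjusted over the list alone (camera adjusted p = 9.06e-08). It included the carbonic anhydrase gene Car1 (-2.69 ± 0.16) and Rhag, part of the Rh complex of red cells (-1.47 ± 0.15). The cell cycle list fell by less per gene, with 24 of 24 members lower, a median of -0.35 and 0 members adjusted over the list alone (camera adjusted p = 1.79e-07). Its proliferation marker Mki67 differed by -0.81 ± 0.13 and the nucleotide synthesis gene Rrm2 by -0.71 ± 0.11. MHC class II genes, which present antigen, rose as a set, with 8 of 8 members higher, a median of 1.30 and 6 adjusted over the list alone (camera adjusted p = 1.86e-07), among them H2-Ab1 (1.74 ± 0.13) and Cd74 (1.55 ± 0.12). The megakaryocyte list rose as a set (camera adjusted p = 2.72e-07), with 6 members adjusted over the list alone. The stem and progenitor list rose, with a median of 1.04 (14 of 21 higher; 11 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00126). In it Meis1 (2.55 ± 0.24) and Erg (1.37 ± 0.13), transcription factors of stem cells, were higher, while Mecom, another such factor, was at -5.07 ± 0.48, with 132 TPM in HMGA2-OE against 2.07 and 5.27.

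In this comparison the limma test called 0 of 12226 genes, and 1908 had an unadjusted p under 0.05, against 611 by chance. The smallest adjusted p was 0.112. The genes with the smallest p among those higher were Cpa3, a mast cell carboxypeptidase (4.43 ± 0.13), Runx1 (3.33 ± 0.12), Ctla2a (2.73 ± 0.13), Tespa1 (2.93 ± 0.16) and Gng11 (4.41 ± 0.26). Among those lower they were Olfm4, the monocyte antigen gene Ly6c2 (-2.16 ± 0.12), Ifitm6 (-2.69 ± 0.15), Nkg7 and Car1. Hmga2 itself differed by -0.08 ± 0.21. By the directional fry test, which does not compare with other genes, 0 lists passed (smallest adjusted p = 0.114). Beside the 10 lists called by camera, the 15 other lists tested did not pass it. Their medians were -0.24 for the HMGA2 and let-7 axis, 0.25 for reported RUNX1 targets, 0.29 for eosinophil, basophil and mast cell markers, 0.17 for B lymphoid markers, 0.05 for the interferon response and 0.33 for NF-kB targets. They were 0.20 for immediate early and heat shock genes, 0.31 for JAK-STAT targets, 0.18 for p53 targets and 0.11 for cholesterol synthesis. Oxidative phosphorylation had a median of -0.11, ribosomal proteins a median of -0.00486 and mitochondrially encoded genes a median of -0.13. For the unfolded protein response the median was 0.25 and the mean -0.08, and for glycolysis the median was 0.01 and the test pointed down, so their signs differ. Stromal and endothelial, T and NK cell and sex-linked lists had fewer than 5 members above the filter and were not tested. The spread comes from the RUNX1mut/HMGA2-OE pair alone, with 1 residual degree of freedom, and the lone HMGA2-OE library is assumed to vary like it. The estimated correlations rest on the same pair, and with them camera called a simulated shifted list in 0 of 5 rounds. Without scaling the median of all genes was 0.14 higher than 0 on the log2 scale, and the 10 called lists kept their direction and call.

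**Figure D3:**
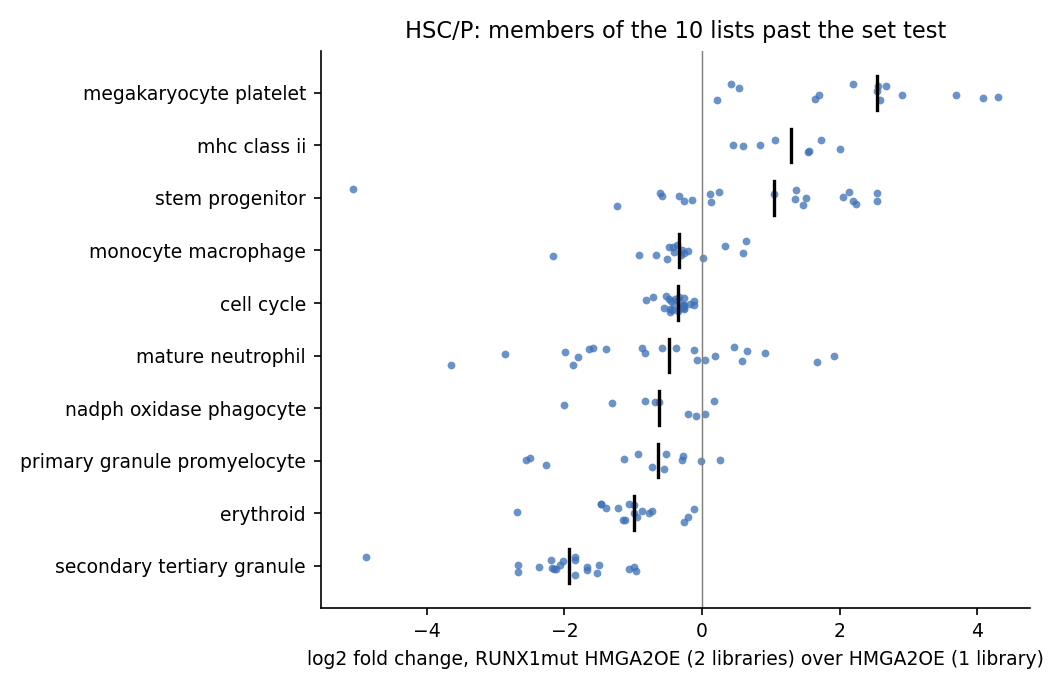
Log2 fold change of RUNX1mut/HMGA2-OE (2 libraries) over HMGA2-OE (1 library) in HSC/P (x axis) for members of the 10 lists that passed the set test (y axis). Each point is a gene and each black bar a list median, from -1.93 for secondary and tertiary granule genes to 2.55 for megakaryocyte and platelet genes.

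The second comparison asked what went with the RUNX1 mutation in Ly6G+ cells, with both mutant libraries set against both others and HMGA2-OE as a covariate. Erythroid, megakaryocyte, monocyte, B lymphoid and MHC class II genes were higher in the mutant libraries, while immediate early genes were lower. The erythroid list had a median of 1.53 (13 of 14 higher, 9 adjusted over the list alone), the megakaryocyte list a median of 1.38 (8 of 9 higher; 8 higher and 1 lower adjusted over the list alone) and the MHC class II list a median of 1.86 (6 of 7 higher, 2 adjusted over the list alone). The immediate early and heat shock list, made up of genes induced within minutes of a stimulus, had a median of -0.70 (7 of 8 lower, 4 adjusted over the list alone). Its member Fos differed by -1.81 ± 0.10 and Dusp1 by -1.34 ± 0.13. With all 7 libraries in an additive fit and the RUNX1mut/HMGA2-OE Ly6G+ library left out, a setting chosen after seeing the data, 11 lists passed, and the erythroid (median 0.01), monocyte (0.21) and immediate early lists (-0.09) did not. That fit also takes in the HSC/P libraries, where these medians were -0.99, -0.33 and 0.20. In the Ly6G+ pair of RUNX1mut over Control they were 1.33, 0.97 and -0.70.

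The 9 lists that rose, each at adjusted p = 0.607 with an estimated correlation, included erythroid (camera adjusted p = 7.99e-07), megakaryocyte (1.07e-04), MHC class II (0.00305), and monocyte and macrophage genes (median 0.90, 11 of 13 higher; 5 higher and 1 lower adjusted over the list alone; 1.78e-04). Members were the globin gene Hbb-bt (2.61 ± 0.32), the platelet chemokine gene Pf4 (2.77 ± 0.17), H2-Eb1 (2.73 ± 0.32) and the complement gene C1qb (1.17 ± 0.14), against -1.42 ± 0.26 for Ly6c2. B lymphoid genes also rose (median 0.80, 8 of 9 higher, 2 adjusted over the list alone; 0.00107), including the surrogate light chain gene Igll1 (1.74 ± 0.19). The stem and progenitor list (median 0.57, 9 of 13 higher, 0 adjusted over the list alone; 0.0128) and the reported RUNX1 targets (median 0.57, 9 of 13 higher, 2 adjusted over the list alone; 0.0437) rose too, and with upper-quartile scaling the RUNX1 targets no longer passed. Ribosomal protein genes (median 0.50, 18 of 22 higher, 0 adjusted over the list alone; 3.84e-05) and mitochondrially encoded genes (median 0.43, 10 of 10 higher, 0 adjusted over the list alone; 1.81e-04) completed the set, with Rpl32 at 0.94 ± 0.11.

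The 8 lists that fell were immediate early and heat shock (camera adjusted p = 1.81e-04), NF-kB targets (median -0.47, 13 of 15 lower; 0.00467), cholesterol synthesis (-0.35, 12 of 14 lower; 0.00222), glycolysis (-0.33, 13 of 15 lower; 0.00107), mature neutrophil (-0.30, 17 of 22 lower; 0.00528), NADPH oxidase (-0.29, 9 of 9 lower; 0.00126), secondary and tertiary granule (-0.18, 14 of 20 lower; 0.0141) and p53 targets (-0.17, 8 of 10 lower; 0.0437). With an estimated correlation the cholesterol list had adjusted p = 0.608 and the other 7 adjusted p = 0.607. Without scaling the median of all genes was 0.58 higher on the log2 scale, the medians of 7 of these 8 lists were then above 0, among them NF-kB targets at 0.18 and mature neutrophil at 0.38 (the immediate early list stayed below), and 10 of the 17 called lists kept their call. In the additive fit to 7 libraries without RUNX1mut/HMGA2-OE Ly6G+ the NF-kB median was 0.02. Adjusted over the list alone, 1 mature neutrophil gene was higher and 1 lower, and 0 passed in the other 6 beside the immediate early list. In the mature neutrophil list the cystatin-like gene Stfa2 differed by 3.45 ± 0.35 and the membrane protease gene Mmp25 by -1.03 ± 0.11. Glycolysis included the lactate dehydrogenase gene Ldha (-0.94 ± 0.12), and cholesterol synthesis Sc5d (-0.84 ± 0.11). By the directional fry test, which does not compare with other genes, only p53 targets passed (adjusted p = 0.0159). Among random lists matched on expression, NADPH oxidase genes were at percentiles 5.44 and 19.62 without and with HMGA2-OE. Secondary granule genes were at 3.35 and 84.26 and p53 targets at 7.76 and 5.12. These lists lay within the range of random lists in both pairs. Mature neutrophil (24.94 and 0.24), NF-kB (18.57 and 0.01), cholesterol (0.11 and 7.08) and glycolysis lists (2.1 and 10.45) lay outside it in 1 pair. Immediate early genes (0.02 and 0.09) did in both.

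The limma test of the RUNX1 term called 0 of 9820 genes, with 1413 at an unadjusted p under 0.05 against 491 by chance and a smallest adjusted p of 0.328. Genes with the smallest p were Ms4a6b (2.62 ± 0.13), the opioid precursor gene Penk (3.02 ± 0.18), BC100530 (2.45 ± 0.15), Pf4 and Snhg15 (2.34 ± 0.15) among those higher, and Fos, Rbm3os (-2.55 ± 0.15), Sema4f (-2.03 ± 0.13), Atp6v0a1 (-1.56 ± 0.10) and the tight junction gene Cldn1 (-2.48 ± 0.16) among those lower. Of these, BC100530, Pf4, Snhg15, Rbm3os and Atp6v0a1 have an annotated transcript of 350 to 420 nt. Runx1 differed by 1.26 ± 0.12 and Hmga2 by 0.14 ± 0.22. Lists that did not pass had medians of 0.14 for the HMGA2 and let-7 axis, 0.39 for primary granule, 1.13 for eosinophil, basophil and mast cell markers, 0.72 for T and NK cell markers, 0.11 for the interferon response, -0.19 for JAK-STAT targets, 0.07 for the cell cycle, 0.28 for the unfolded protein response and 0.09 for oxidative phosphorylation. The 1 residual degree of freedom is the interaction of the genotypes, which is counted as error.

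The same 4 libraries were used for HMGA2-OE in Ly6G+ cells, with the RUNX1 mutation as a covariate. Hmga2 differed by 1.59 ± 0.22 and Igf2bp2, which encodes an mRNA-binding protein and is a known HMGA2 target, by 3.18 ± 0.64. Both passed when adjusted over their list alone, the HMGA2 and let-7 axis, which rose (median 0.33, 5 of 5 higher; camera adjusted p = 0.00899). This list and the 6 others called for this term each had adjusted p = 0.967 with an estimated correlation. The erythroid list passed (median 0.66, 12 of 14 higher; 0.00619), but its median was 0.18 in HMGA2-OE over Control, within the range of random lists, against 0.83 in RUNX1mut/HMGA2-OE over RUNX1mut, and -0.43 in the additive fit to 7 libraries without RUNX1mut/HMGA2-OE Ly6G+. T and NK cell markers rose (0.48, 4 of 5 higher; 0.0354), with the T cell receptor gene Trac at 2.05 ± 0.18. Glycolysis (0.13, 14 of 15 higher; 0.0354) and NADPH oxidase genes (0.15, 9 of 9 higher; 0.0385) rose by little. Among random lists matched on expression, glycolysis was at percentiles 72.57 and 81.38 without and with the RUNX1 mutation. NADPH oxidase genes were at 66.23 and 80.98, so these lists lay within the range of random lists. B lymphoid genes (-0.33, 9 of 9 lower; 0.00899) and cholesterol synthesis genes (-0.33, 12 of 14 lower; 6.42e-04) fell, the first with the surrogate light chain gene Igll1 at -1.44 ± 0.19. The HMGA2 and let-7 axis, which includes Hmga2 itself, was at percentiles 95.4 and 98.07 without and with the RUNX1 mutation. T and NK cell markers were at 99.89 and 89.37, and B lymphoid genes at 9.06 and 0.07. The axis and B lymphoid genes thus lay outside the range of random lists only with the mutation, and T and NK cell markers only without it. Cholesterol synthesis genes, at 0 and 1.55, lay outside it in both pairs.

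Adjusted over the list alone, Trac was the 1 T and NK cell marker to pass, and 0 genes passed in the erythroid, glycolysis, NADPH oxidase, B lymphoid and cholesterol lists. The limma test of this term called 0 of 9820 genes, with 642 at an unadjusted p under 0.05 against 491 by chance and a smallest adjusted p of 0.238. The planned additive fit to all 7 libraries called 57 genes, 8 higher and 49 lower, and 61 were called without scaling. The smallest p among higher genes belonged to Asprv1 (2.29 ± 0.10), the neurotrophin receptor gene Ngfr (4.29 ± 0.19), Sema4d (1.88 ± 0.11), Serhl (1.70 ± 0.12) and Ankrd37 (3.26 ± 0.23). Among lower genes it belonged to Atp5k (-6.18 ± 0.18), Tgtp2 (-3.25 ± 0.12), Phf20 (-3.05 ± 0.14), Spns2 (-5.32 ± 0.24) and Fchsd1 (-3.09 ± 0.14), each of which has an annotated transcript of 350 to 420 nt. So do Sema4d, Serhl, Ankrd37, Igf2bp2 and Trac, while Asprv1, Ngfr and Hmga2 do not. Ngfr was at 11.4 and 36.8 TPM in the Ly6G+ libraries with HMGA2-OE, at 0.05 and 0.06 TPM in those without, and between 155 and 183 TPM in HSC/P. Runx1 differed by 0.19 ± 0.12. Without genes that have such a transcript, a setting chosen after seeing the data, 4 of 7192 genes passed: Ngfr (4.28 ± 0.19) and Asprv1 (2.28 ± 0.09) rose, and Gm10774 (-6.17 ± 0.15) and Gm17333 (-4.21 ± 0.16), named only because they passed, fell. The other 19 lists did not pass, with medians from -0.44 for MHC class II to 0.21 for mitochondrially encoded genes. For stem and progenitor genes, reported RUNX1 targets and the interferon response the median was -0.02 in each, and median, mean and test differed in sign. With at least 5 TPM required in 2 libraries 0 lists passed, and without scaling, where the median of all genes was 0.13 higher, the glycolysis (camera adjusted p = 0.705) and NADPH oxidase lists (0.903) were no longer called.

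Single Ly6G+ libraries were also set against each other, with no replicate check and no p. Against Control, 526 genes were at least 2-fold higher and 350 lower in RUNX1mut, 322 and 312 in HMGA2-OE, and 654 and 577 in RUNX1mut/HMGA2-OE. Of 9820 genes, 146 were at least 2-fold higher with the RUNX1 mutation in both pairs (RUNX1mut over Control, RUNX1mut/HMGA2-OE over HMGA2-OE) and 119 at least 2-fold lower, where independence would give 25.8 and 17.5. These 2 pairs share no library. For HMGA2-OE (HMGA2-OE over Control, RUNX1mut/HMGA2-OE over RUNX1mut) the counts were 57 higher and 132 lower, where independence would give 12.8 and 13.7. The counts depend on the settings. For the mutation they were 476 higher and 49 lower without scaling, and 30 higher and 50 lower with 5 TPM added. With 0.5 TPM added 237 were higher with the mutation, and with 5 TPM added 19 were higher with HMGA2-OE. The Pearson r of the pairs across genes, which are not independent replicates, was 0.28 for the mutation and 0.23 for HMGA2-OE. Leading the genes higher with the mutation were Stfa2, Penk, Stfa3, Ms4a6b, Pf4, Runx3, BC100530, Grap, H2-Eb1 and Snhg15, and leading those lower Hist2h2aa1, Rbm3os, Lmo1, Cldn1, Defb40, Ifitm1, Ms4a15, Nfib, Wdr75 and Sema4f. Stfa2 stood at 29.4, 227, 83.0 and 1347 scaled TPM in Control, RUNX1mut, HMGA2-OE and RUNX1mut/HMGA2-OE, and Ifitm1, an interferon-induced membrane protein gene, at 239, 53.3, 792 and 34.6. Higher with HMGA2-OE were Ngfr, Ankrd37, Morc2a, Asprv1, Igf2bp2, Abcg3, Trac, Sema4d, Pramel5 and Serhl. Lower were Hist1h2aj, Atp5k, Spns2, Tmem254a, Rpl38, Grb2, Slc30a9, Glul, Tgtp2 and St3gal6. Of these 4 sets of 10, 5, 5, 7 and 10 genes have an annotated transcript of 350 to 420 nt, and without such genes the counts were 94, 62, 28 and 13.

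List medians were compared between pairs that share no library. The interferon response had a median log2 ratio of 0.58 in RUNX1mut over Control (18 of 20 higher, 100th percentile of 10000 random lists matched on expression), against -0.23 in RUNX1mut/HMGA2-OE over HMGA2-OE (15 of 20 lower). It stood at 0.30 in HMGA2-OE over Control (18 of 20 higher, 99.96th percentile), against -0.28 in RUNX1mut/HMGA2-OE over RUNX1mut (19 of 20 lower). Gene by gene both comparisons hold the same difference of the 4 libraries. MHC class II stood at 2.65 in RUNX1mut over Control and at 1.06 in RUNX1mut/HMGA2-OE over HMGA2-OE. The primary granule list stood at 0.87 in RUNX1mut over Control and at 0.15 in RUNX1mut/HMGA2-OE over HMGA2-OE. Eosinophil, basophil and mast cell markers stood at 2.13 in RUNX1mut over Control, led by the eosinophil granule gene Prg2 (3.58), and at -0.51 in RUNX1mut/HMGA2-OE over HMGA2-OE, where 4 of 9 members were higher, among them Prg2 (1.51), and 5 lower. Cholesterol synthesis stood at -0.39 in RUNX1mut over Control and at -0.15 in RUNX1mut/HMGA2-OE over HMGA2-OE, and at -0.45 in HMGA2-OE over Control and -0.21 in RUNX1mut/HMGA2-OE over RUNX1mut. The interleukin gene Il1b was at 597 TPM in Control, 722 in RUNX1mut, 2337 in HMGA2-OE and 415 in RUNX1mut/HMGA2-OE. The erythroid list stood at 2.06 in RUNX1mut/HMGA2-OE over Control, with Hbb-bs at 3124 scaled TPM against 35.9. Hbb-bs has an annotated transcript of 350 to 420 nt, and its neighbour Hbb-bt was at 265 TPM in RUNX1mut/HMGA2-OE where Hbb-bs was at 4934, against 61.6 and 116 in RUNX1mut.

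**Figure D4:**
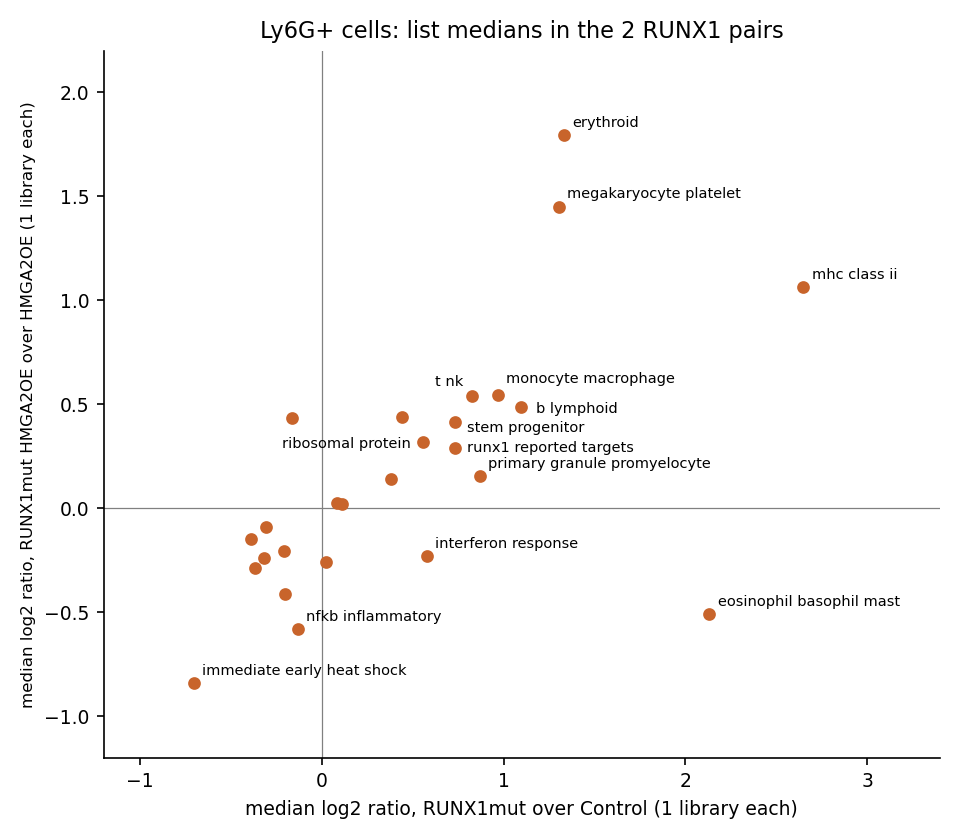
Median log2 ratio of each fixed list in Ly6G+ cells for RUNX1mut over Control (x axis) and for RUNX1mut/HMGA2-OE over HMGA2-OE (y axis), 1 library each, 1 point per list, with no test. Erythroid (1.33 and 1.79) and megakaryocyte (1.30 and 1.45) lists are higher in both, and eosinophil, basophil and mast cell markers (2.13 and -0.51) are not.

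The effect of the RUNX1 mutation on top of HMGA2-OE was next fitted over both cell types, in 5 libraries. Runx3 (3.70 ± 0.20), which has an annotated transcript of 350 to 420 nt, the serpin gene Serpina3g (2.03 ± 0.15), H2-Eb1 (2.16 ± 0.17), Gimap6 (1.84 ± 0.15) and Camk1 (1.39 ± 0.13) had the smallest p among higher genes. Among lower genes they were Spp1, which encodes osteopontin (-2.33 ± 0.17), Ly6c2 (-2.05 ± 0.15), Lmo1 (-3.29 ± 0.30) and Cystm1 (-1.82 ± 0.18). Gimap6, Spp1 and Cystm1 also have such a transcript. Megakaryocyte genes (median 1.603, 13 of 14 higher, 2 adjusted over the list alone; camera adjusted p = 2.80e-07), MHC class II genes (1.06, 8 of 8 higher, 5 adjusted over the list alone; 1.42e-07), stem and progenitor genes (0.66, 16 of 21 higher, 6 adjusted over the list alone; 4.73e-05) and B lymphoid genes (0.27, 11 of 12 higher, 0 adjusted over the list alone; 0.0101) rose. Cd34, a surface antigen of progenitors, was at 1.95 ± 0.28. Secondary and tertiary granule (-1.19, 20 of 20 lower, 0 adjusted over the list alone; 1.20e-09), NADPH oxidase (-0.48, 8 of 9 lower, 1 adjusted over the list alone; 5.16e-04), cell cycle (-0.21, 18 of 24 lower, 0 adjusted over the list alone; 9.40e-04), mature neutrophil (-0.43, 16 of 22 lower, 1 adjusted over the list alone; 0.00491) and primary granule genes (-0.44, 10 of 12 lower, 0 adjusted over the list alone; 0.0213) fell. With an estimated correlation the adjusted p was 0.570 for the stem, MHC class II, mature neutrophil and NADPH oxidase lists, 0.884 for megakaryocyte, 0.897 for secondary granule and 0.934 for B lymphoid, primary granule and cell cycle. In HSC/P and in Ly6G+ cells apart, the medians were -1.93 and -0.09 for secondary granule genes and -0.35 and 0.03 for the cell cycle. For primary granule genes they were -0.64 and 0.15, so these falls were mostly those of HSC/P. NADPH oxidase (-0.62 and -0.29) and mature neutrophil genes (-0.48 and -0.41) were below 0 in both. By the directional fry test 0 lists passed (smallest adjusted p = 0.218). The other 16 lists did not pass camera. Among them the median, mean and test differed in sign for monocyte (median 0.12, mean -0.01), eosinophil (-0.12 and 0.22), unfolded protein response (0.11 and -0.09) and oxidative phosphorylation (-0.09 and 0.05).

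The limma test called 0 of 12686 genes here, with 1008 at an unadjusted p under 0.05 against 634 by chance and a smallest adjusted p of 0.330. Runx1 differed by 2.44 ± 0.49 and Hmga2 by 0.13 ± 0.20. Without scaling the median of all genes was 0.48 higher and 4 of the 5 lower lists had a median above 0, all but the secondary granule list. The B lymphoid (camera adjusted p = 0.171) and cell cycle lists (0.509) were then no longer called. Without the HMGA2-OE HSC/P library, 1 gene passed, ENSMUSG00000060214, which has no symbol and is named only because it passed (-11.97 ± 0.13), and the cell cycle median was -0.02 with the test pointing up.

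HSC/P were compared with Ly6G+ cells in the same 5 libraries, which asks whether the libraries carry the markers of their labels. Mature neutrophil genes were lower in HSC/P (median -5.34, 21 of 22 lower, 20 of them called), as were secondary and tertiary granule genes (-5.55, 20 of 20 lower, 19 called) and NADPH oxidase genes (-4.23, 9 of 9 lower and called). The resistin-like gene Retnlg fell by 10.24 on the log2 scale and the collagenase gene Mmp8 differed by -9.66 ± 0.39. Stem and progenitor genes were higher in HSC/P (2.04, 19 of 21 higher; 15 higher and 1 lower called), including Tal1 (4.39 ± 0.21) and Gata2 (3.48 ± 0.21), and Spi1 was lower (-4.11 ± 0.30). Ribosomal protein genes (2.71, 22 of 22 called higher) and mitochondrially encoded genes (2.47, 10 of 10 called higher) were also higher in HSC/P. Kit, the receptor used for the HSC/P enrichment and singled out after its values were seen, was at 61.8, 155 and 134 TPM in HSC/P and between 3.43 and 5.20 TPM in Ly6G+ cells.

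Between the cell types the limma test called 8201 of 12686 genes, 4060 higher and 4141 lower in HSC/P, so 49.5% were higher. That split depends on the scaling, with 65.0% higher under upper-quartile scaling and 87.9% without scaling, where the median of all genes was 0.55 and 1.46 on the log2 scale. Leading the higher genes were Rpl37rt (9.61 ± 0.21), mt-Nd4l (7.67 ± 0.20), mt-Nd3 (7.05 ± 0.23), Ybx3 (6.58 ± 0.28), Igkv11-106 (6.43 ± 0.92), Zfpm1 (5.67 ± 0.29), Hnrnpa0 (5.59 ± 0.19), Pabpc4 (5.46 ± 0.35), Rpl38 (5.41 ± 0.15) and Snrpg (5.08 ± 0.23). Leading the lower genes, beside Retnlg and Mmp8, were Il1b, Stfa2l1, Mmp9, Stfa3, Ccl6, Fpr1, Cyp4f18 and Stfa2, with log2 changes from -9.63 to -7.92. Hmga2 was 2.41 ± 0.20 higher in HSC/P (adjusted p = 0.00142), and Runx1 differed by 1.09 ± 0.49 (adjusted p = 0.115), or by -0.08 without the RUNX1mut/HMGA2-OE Ly6G+ library. Of 25 lists 11 passed camera. Beside those above they were megakaryocyte (2.58, adjusted p = 0.00871) among the higher, and interferon response (-2.34, 4.39e-04), NF-kB targets (-2.51, 0.00243), immediate early and heat shock (-2.75, 0.00277) and glycolysis (-2.27, 4.39e-04) among the lower. The camera adjusted p was 3.30e-07 for secondary granule, 2.12e-06 for mature neutrophil, 3.71e-05 for NADPH oxidase, 0.00166 for stem, 1.29e-07 for ribosomal and 3.54e-04 for mitochondrially encoded genes. With an estimated correlation 0 of the 11 passed, at adjusted p between 0.541 and 0.762, while fry called 12 lists. The 14 others had medians from -1.19 for JAK-STAT targets to 2.42 for reported RUNX1 targets, and for the HMGA2 and let-7 axis, eosinophil, B lymphoid, MHC class II and cholesterol lists median, mean and test differed in sign.

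Whether the effect of the mutation on top of HMGA2-OE differs between cell types was tested as an interaction. Erythroid genes were lower in HSC/P (median -0.99) and higher in Ly6G+ cells (1.79), and secondary granule genes were lower by more in HSC/P (-1.93 against -0.09). NF-kB targets had a median of 0.33 in HSC/P, where the list did not pass (camera adjusted p = 0.142), and of -0.58 in Ly6G+ cells. Without scaling their interaction median was 0.0362. The difference passed, adjusted over the list alone, for 16 of 17 erythroid genes, for 9 of 20 secondary granule genes, led by Olfm4, and for 2 of 14 NF-kB targets, the chemokine gene Ccl3 (2.28 ± 0.31) and Il1b. The spread comes from the RUNX1mut/HMGA2-OE HSC/P pair alone, and the Ly6G+ libraries, 1 per genotype, are assumed to vary like it. More genes ranged widely among Ly6G+ libraries (3.09%) than among HSC/P libraries (0.830%). That range spans 4 Ly6G+ libraries of 4 genotypes against 3 HSC/P libraries with a replicate pair, so it does not measure the spread between replicates. Without scaling the median of all genes was -0.77 and 3 of the 12 called lists were no longer called. Without a filter on low TPM only 3 lists were called, while 3443 of 22002 genes were called in place of 0. The limma test called 0 of 12686 genes, with 2298 at an unadjusted p under 0.05 against 634 by chance and a smallest adjusted p of 0.125, and 12 lists passed camera, 5 higher and 7 lower, each with adjusted p = 0.789 with an estimated correlation. The 13 others had medians from -0.89 for primary granule genes to 1.53 for megakaryocyte genes, and median, mean and test differed in sign for stem, mature neutrophil and unfolded protein response genes. Genes with the smallest p were Romo1 (5.71 ± 0.18), Rps29, Cox15, Ndufb4c and Grb14 on one side and Hibch (-4.14 ± 0.18), Naa38, Olfm4 (-5.94 ± 0.28), Ccdc43 and Nop56 on the other, and of these 10 all but Olfm4 have an annotated transcript of 350 to 420 nt. Runx1 differed by 1.98 ± 0.18 and Hmga2 by -0.46 ± 0.34. By the directional fry test 0 lists passed in the interaction (smallest adjusted p = 0.122). Across 9305 genes the HSC/P effect and the Ly6G+ ratio had a Pearson r of 0.07. At least 2-fold higher in both were 54 genes where independence would give 15.0, and lower in both 44 where it would give 12.1.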

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

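The tests of the 3 patterns weighed here were all chosen after the results were seen, while the interaction test and the pairs were planned. For 12 lists the effect of the RUNX1 mutation on top of HMGA2-OE differed between HSC/P and Ly6G+ cells by camera on the limma interaction, each with adjusted p = 0.789 with an estimated correlation. By the directional fry test 0 lists passed (smallest adjusted p = 0.122). The values are medians over genes of the HSC/P minus the Ly6G+ log2 change, followed by the median in each cell type. Erythroid genes differed by -2.80 (-0.99 and 1.79; camera adjusted p = 2.02e-11), secondary and tertiary granule genes by -1.58 (-1.93 and -0.09; 2.95e-09), monocyte and macrophage genes by -0.77 (-0.33 and 0.54; 0.0116) and the HMGA2 and let-7 axis by -0.46 (-0.24 and 0.43; 0.0251). Mitochondrially encoded genes differed by -0.45 (-0.13 and 0.44; 0.0250), cell cycle genes by -0.33 (-0.35 and 0.03; 8.89e-04) and ribosomal protein genes by -0.25 (-0.00486 and 0.32; 0.0465). Immediate early and heat shock genes differed by 1.63 (0.20 and -0.84; 0.0324), JAK-STAT targets by 1.11 (0.31 and -0.26; 0.0324), NF-kB targets by 0.96 (0.33 and -0.58; 3.37e-04), p53 targets by 0.36 (0.18 and -0.21; 0.0427) and glycolysis by 0.27 (0.01 and -0.24; 0.0324). Without scaling the median of all genes in this comparison was -0.77, and the medians were 0.0545 for JAK-STAT targets, 0.0362 for NF-kB targets, -0.70 for p53 targets and -0.85 for glycolysis. The monocyte (camera adjusted p = 0.174), p53 (0.126) and glycolysis (0.707) lists were then no longer called, 3 of the 12. Without a filter on low TPM only 3 lists were called, the erythroid, secondary and tertiary granule and NF-kB lists. The spread of the interaction comes from the RUNX1mut/HMGA2-OE HSC/P pair alone, and each Ly6G+ library is assumed to vary like it.

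In Ly6G+ cells 9 comparisons of list medians went opposite ways in the pairs with both medians outside the central range of the matched random lists. Each pair is 1 library against 1, and these differences were not tested. All 9 rest on the same 4 libraries, and the negative median was always in the pair with RUNX1mut/HMGA2-OE. Gene by gene the difference is the same contrast for the RUNX1 mutation and for HMGA2-OE. The eosinophil and interferon lists appear under both, so for each a single contrast is counted again. The sizes given for them differ only because medians were subtracted. For the RUNX1 mutation, without and with HMGA2-OE, eosinophil, basophil and mast cell markers differed by 2.64 (2.13 and -0.51) and the interferon response by 0.81 (0.58 and -0.23). For HMGA2-OE, without and with the RUNX1 mutation, the same eosinophil, basophil and mast cell markers differed by 1.4997 (0.58 and -0.92), MHC class II genes by 1.48 (0.35 and -1.12), primary granule genes by 1.01 (0.37 and -0.64) and reported RUNX1 targets by 0.66 (0.38 and -0.28). The interferon response differed by 0.58 (0.30 and -0.28), JAK-STAT targets by 0.56 (0.25 and -0.31) and NF-kB targets by 0.52 (0.34 and -0.18).

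Secondary and tertiary granule genes were lower in RUNX1mut/HMGA2-OE than in HMGA2-OE HSC/P. Mature Ly6G+ cells left among the HMGA2-OE HSC/P would bring all their abundant transcripts. The test used 27 Ly6G+ genes of at least 10 TPM, picked as under 2% of their Ly6G+ level in the RUNX1mut/HMGA2-OE pair. Their difference came to a median of 1.62% Ly6G+ RNA (quartiles 0.0409% and 3.86%), where the granule list would need a median of 13.7% (lower quartile 8.07%). The mature neutrophil list came to 0.276%. Its member Ly6g was at 136 TPM in HMGA2-OE HSC/P, 7.28 and 16.8 TPM in the pair and 270 TPM in HMGA2-OE Ly6G+ cells. Its member S100a9 was at 19224, 4956 and 5953 TPM in the same HSC/P libraries and at 70749 TPM in those Ly6G+ cells. Neither was among the 27 genes, so the test speaks only for the genes picked. Scaling is argued against by the list's median of -1.77 without any. Camera compares the list with other genes, which scaling shifts about alike. Its call without scaling (adjusted p = 9.41e-27) therefore does not bear on this. A different share of immature granulocytic cells and an effect of the RUNX1 genotype within cells both stay open, were not tested, and may act together.

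Markers of other cell types were higher in the RUNX1mut Ly6G+ libraries, with 52 of 59 higher without HMGA2-OE and 48 of 59 higher with it. A lower share of neutrophils would raise the markers of every other cell type, but not by equal log2 ratios, since 1 TPM was added and the lists differ in abundance. Without HMGA2-OE, RUNX1mut over Control, the medians of 6 lists lay between 0.82 and 2.13 and a permutation test of the lists gave p = 0.196. With HMGA2-OE they ranged from -0.51 for eosinophil, basophil and mast cell markers to 1.79 for erythroid genes (permutation p = 2.30e-04). The test shuffled genes between lists as if independent, and each pair is 1 library against 1. It therefore does not measure variation between libraries and cannot decide whether a lower share is the cause in either pair. A lower share stays open, and carry-over of particular cell types through the Ly6G sort and an effect of the genotype stay open and untested.

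Among Ly6G+ libraries 171 of 5528 genes at 10 TPM or more ranged over at least 16-fold (3.09%), against 73 of 8790 in HSC/P (0.830%). In 90 of the 171 the RUNX1mut/HMGA2-OE library was the farthest from the median. The Ly6G+ range spans 4 libraries of 4 genotypes and the HSC/P range 3 libraries with a replicate pair, so the percentages are not like for like. These TPM were unscaled, and that Ly6G+ library had the largest scaling factor (1.58). Of those with an annotation 83.4% had a transcript of 350 to 420 nt against 29.3% of other genes (odds ratio 12.1), and in HSC/P the odds ratio was 0.598, which is consistent with an abundance estimate that breaks down for transcripts near the fragment length in the Ly6G+ libraries, though the window was chosen after the lengths were seen. Reads shared with pseudogene copies could account for a part, since among genes with such a transcript the odds ratio of being a pseudogene was 18.04, with 26 of 136 genes. For S100a8, whose transcripts are 486 and 498 nt long, such a breakdown and a difference between cells cannot be told apart from the ratio of 0.216 to S100a9, because the pattern is in 1 library with no replicate. An effect of the genotypes on these genes was not tested.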

How the results depend on the processing

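In the tested comparisons the settings without scaling, without a variance trend, with robust variances and with 0.5 or 5 TPM added, and everywhere those without transcripts under 300 nt or of 350 to 420 nt and without the HMGA2-OE or a Ly6G+ library, including the additive fit to 7 libraries without Ly6G+ RUNX1mut/HMGA2-OE, were chosen after seeing the data. Depth is unknown, so no counting error can be given, and each Ly6G+ genotype is 1 library, assumed to vary like the others. Of the values of named genes under the alternatives, 4301 kept direction and call, 209 untested ones moved beyond the replicate spread, 68 newly passed, 3 no longer passed and 38 reversed. Of the list results 832 were the same, 93 were no longer called and 6 reversed. Without scaling, more called lists had a median that changed sign: 7 for the RUNX1 term, 4 over both cell types and 2 in the interaction. Of these only glycolysis in the interaction is counted as reversed. Of the counts 167 were the same, 12 rose and 13 fell. The cause was not tested except where the setting itself removes genes or libraries. The planned DESeq2, limma-voom and legacy quasi-likelihood fits were not run, since they need counts. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.

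Without scaling, limma called 1 gene in HSC/P (Cpa3, named because it passed) in place of 0, with Hmga2 at 0.0855. The RUNX1 term in Ly6G+ cells then had 133 genes called and the HMGA2-OE term 61, both in place of 0. For the RUNX1 term Adpgk and Ngp were then at 0.22, Zfp36 at 0.12, Nfkbiz at 0.29, Sesn2 at 0.18, Mdm2 at 0.43, Mvd at 0.25, Pgam1 at 0.0276, Eno1 at 0.21, Gpi1 at 0.14, Fcer1g at 0.24, Rac2 at 0.28 and Ncf1 at 0.34, all below 0 in the reported fit. Over both cell types 88 genes were called in place of 0, with Aurkb at 0.15, Bub1 at 0.00515, Rrm2 at 0.13, Mki67 at 0.0453, Ncf4 at 0.0470 and Cyba at 0.16. In the interaction Eno1 was at -0.47, Pfkl at -0.46, Rpl18 at -0.34, mt-Nd3 at -0.32 and the glycolysis median at -0.85. In the pairs for the RUNX1 mutation 476 genes were higher in both, in place of 146, and 49 lower, in place of 119.

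In the additive fit to all 7 libraries the RUNX1 term had 11 lists in place of 17, Hmga2 at -0.0023 and Retnlg at -0.0338, and the HMGA2-OE term had 57 genes in place of 0 and 4 lists in place of 7. In that fit without Ly6G+ RUNX1mut/HMGA2-OE, the RUNX1 term had 11 lists, with Hmga2 at -0.17, Clec4e at 0.0940, Retnlg at -0.27, Zfp36 at 0.17, Junb at 0.00571, the erythroid median at 0.0111 and the NF-kB median at 0.0217. The HMGA2-OE term then had 45 genes, with Klf1 at -0.0449, Hbb-bt at -0.24, Ncf1 at -0.15 and the erythroid median at -0.43.

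With at least 5 TPM the HMGA2-OE term had 0 lists in place of 7, and the interaction 1 gene (ENSMUSG00000060214, without a symbol and named because it passed) in place of 0. Without a filter the interaction had 3443 genes and 3 lists, in place of 0 and 12. Without genes that have a transcript of 350 to 420 nt the HMGA2-OE term had 4 genes in place of 0. In the pairs, the genes higher and lower with the RUNX1 mutation then numbered 94 and 62, and with HMGA2-OE 28 and 13, where fewer genes are compared. With 0.5 TPM added, 237 genes were higher with the mutation in both pairs, and with 5 TPM added 30, with 50 lower, and 19 higher with HMGA2-OE.

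Leaving out each replicate or library in turn, Hmga2 in the HSC/P comparison ranged from -0.28 to 0.12 and the monocyte and macrophage median from -0.64 to 7.05e-05. Over both cell types 0 to 1 genes and 9 to 12 lists were called, Hmga2 ranged from -0.0722 to 0.42 and the cell cycle median from -0.34 to -0.0226. Between HSC/P and Ly6G+ cells 6397 to 7927 genes and 11 to 13 lists were called, and Runx1 ranged from -0.0751 to 1.92.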

Other observations

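No test in this part was planned, and the genes were chosen after their values were seen. A pair of ribosomal protein genes split within the replicate pair of RUNX1mut/HMGA2-OE HSC/P: Rps27 was at 16250 TPM in replicate 1 and 2.63e-06 in replicate 2, and listed at 0 in the 5 other libraries, while Rps15a was at 1669 and 17261 TPM. The near copy Rps27rt was at 9483 and 8794 TPM in the same pair and at 7504 TPM in HMGA2-OE HSC/P. Over all genes compared, the median absolute difference between these replicates was 0.18 on the log2 scale.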
